A study of Danio rerio with 15 samples.

How the data were processed

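Expression was measured in Müller glia sorted by flow cytometry from retinas of a gfap:GFP zebrafish line, at 0 (unlesioned), 8, 16, 24 and 36 hours post-lesion (hpl), with 3 biological replicates per time. Total RNA was linearly amplified, labelled with biotin and hybridised to Affymetrix zebrafish arrays, 1 per replicate. The deposited values were log2 values made by RMA (background correction, quantile normalisation and median-polish summary of probes) according to the submitters' processing notes, and the RMA implementation and its version are not given in the sources used here. A second deposited table holds the authors' own comparisons for 3164 probe sets: the authors' signed fold changes against 0 hpl and the authors' p-values, one per time and a smallest value over the times, adjusted in a way the file does not describe and with a test it does not state. Its fold changes equalled the differences of group means of the value table to 6.93e-10 on the log2 scale.

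Samples were grouped by time as labelled, and no column of values was left unmapped. The 115 Affymetrix control probe sets were left out, and no filter on dim probe sets was used, because RMA values carry no detection calls. A linear model with 1 coefficient per time was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that the groups share an estimate of the spread. Contrasts compared each time with 0 hpl and each time with the one before. Probe sets were called at a Benjamini-Hochberg adjusted p under 0.05 over the 15502 tested, and a moderated F test over the 4 contrasts against 0 hpl covered the whole course. Changes are log2 differences with the standard error (SE) of the fit. Replicates came from separate biological samples, and the number of arrays limits the precision.

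Gene names came from the authors' deposited table, updated with a table of RefSeq symbols and synonyms. Of its 3164 probe sets 2511 carried 1 symbol, 108 several and 545 none. Of the 2511, 1983 matched the RefSeq table (969 by a current symbol, 38 by one that is also a synonym of another gene, 976 by a synonym that was updated) and 528 were kept as given. This gave 2331 genes, of which 1810 have more than a clone or locus name. All 3164 probe sets changed at least 2-fold at 1 or more times, as did 197 that are not in that table, so genes below this size are not named here. A gene is represented by its probe set with the highest mean over all arrays.

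The design, the alternatives, 34 gene lists and the rule for named genes were fixed before the data were examined. The rule took, for each time against 0 hpl, the 8 largest rises and 6 largest falls among called probe sets with 1 symbol whose 3 arrays lie outside the range of the controls, with clone and locus names left out. It added up to 4 members with the smallest adjusted p of each list described, a panel of genes known from retinal regeneration, and the 4 largest rises and 4 largest falls of each consecutive contrast. The text names most, not all, of the genes this picks. The panel included glula, rlbp1a, gnat1, ascl1a, stat3, socs3a, pcna, mcm5, ccnd1, hspd1, ttk, sox2, mmp9 and atf3, and also gfap, pax6a, pax6b, notch1a, fabp7a, junbb, her4.1 and her6, which are not named among the probe sets used here.

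The lists covered DNA replication, mitosis and G2/M, G1/S regulators, Müller glia reprogramming, Müller glia identity, photoreceptors, other retinal neurons, microglia, pigment epithelium, red blood cells, endothelial and mural cells, oligodendrocytes and astrocytes, lens crystallins, chaperones, immediate early genes, Jak-Stat signalling, complement, extracellular matrix, cytoskeleton, cholesterol synthesis, ribosome biogenesis, ribosomal proteins, the proteasome, glycolysis and hypoxia, oxidative phosphorylation, chromatin, Notch, Wnt, FGF with TGF-beta and BMP, retinoic acid, the clock, p53 with DNA damage, ER stress, and oxidative stress with iron. They name 2174 genes, of which 586 are named here. The 28 lists with at least 5 named members were tested with limma's camera at a preset inter-gene correlation of 0.01 against the other named genes, adjusted over lists within a contrast, and with a correlation estimated per list as an alternative. Members called are counted over all probe sets and also adjusted over the list alone. Sets of cone, rod and inhibitory neuron genes were written after the data were seen.

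Overlaps between times were set beside the number expected of independent lists and beside 20 simulations of unchanged groups against the same controls. Array-level values (hybridisation controls, quartiles) were compared with two-sided exact permutation tests, whose smallest p for 3 against 3 arrays is 0.1. Alternatives were quantile normalisation applied again, median centring, the dimmest 25% left out, eBayes with a trend and robust settings, array weights, a fit on the compared groups alone, replicate number as a block, a 2-fold minimum, an adjusted p under 0.01, the mean of a gene's probe sets, and leaving out each array in turn. Scaling on the hybridisation controls and leaving out the 3 arrays of lowest weight were added after the data were seen. All 10 divisions of the 6 arrays of a contrast into 3 and 3 were fitted, and 100 drawn divisions for the F test.

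The pipeline was tested on simulated data with 67, 67 and 66 probe sets per contrast changed by 0.5, 1 and 2 on the log2 scale. At 0.5 between 5.97% and 16.4% were called over the contrasts, at 1 between 77.6% and 91.0%, and at 2 between 98.5% and 100%. False calls numbered 5 to 9 of 15502. A DNA replication list of 25 genes raised by 1 (log2) was called in 20 of 20 simulations at 36 hpl. Other lists gave 1 call. Lists of correlated genes were not simulated.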

Results

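The data were expression values of retinal Müller glia, the radial glial cells from which the zebrafish retina regrows lost neurons, measured on Affymetrix arrays after a light lesion. Cells carrying a gfap:GFP transgene, whose promoter is active in Müller glia, were sorted by flow cytometry at 8, 16, 24 and 36 hours post-lesion (hpl), and unlesioned fish gave the 0 hpl controls. Each of the 5 groups held 3 biological replicates with 1 array each, 15 arrays in all. The deposited log2 RMA values covered 15617 probe sets, of which 115 were Affymetrix controls and 15502 were tested. Median values per array lay between 4.41 and 4.67 on the log2 scale, and correlations across probe sets between arrays of a group lay between 0.973 and 0.991. No depth in the sense of read counts exists for arrays, so their number limits the precision. The p-values of single probe sets rest on a spread between arrays that is estimated over all 15 arrays together, with 3 per group. Those of the list test at the preset correlation rest on the spread between genes, so a small value there does not measure the spread between arrays.

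**Figure D1:**
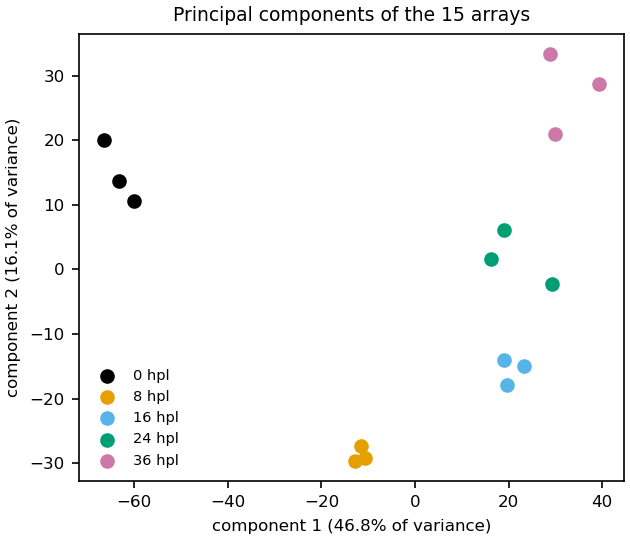
Each point is 1 array, placed by the first and second principal components of the log2 values, and colours mark the 5 times. The first component, with 46.8% of the variance, separates the 0 hpl arrays from the lesioned groups, and the second holds 16.1%.

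The first question was how many transcripts changed at each time after the lesion. At 8 hpl 4108 probe sets passed limma's test at an adjusted p under 0.05, at 16 hpl 6252, at 24 hpl 4722 and at 36 hpl 7217. The rises numbered 1862, 2853, 2522 and 3091 and the falls 2246, 3399, 2200 and 4126, so that 45.3%, 45.6%, 53.4% and 42.8% of the calls were rises. Among the called probe sets 680, 1293, 1241 and 1482 rose at least 2-fold and 372, 660, 718 and 1026 fell at least 2-fold. The moderated F test over all 5 times called 7136 probe sets. The 3 lesioned arrays lay wholly outside the range of the 3 controls for 3856, 6038, 4571 and 6724 of the called probe sets and for 38.6%, 54.1%, 43.8% and 52.5% of all probe sets, where chance gives 10%.

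The balance of rises and falls depended on how the arrays were scaled. The deposited values put the median change of all probe sets at -0.10, -0.14, -0.11 and -0.14 at the 4 times. Spiked hybridisation controls stood against 0 hpl at -0.44, -0.56, -0.45 and -0.67 on the log2 scale (two-sided exact permutation p of 0.2, 0.1, 0.1 and 0.1, of which 0.1 is the smallest that 3 against 3 arrays can give). With the arrays scaled on those controls, an alternative added after the data were seen, the median change became 0.34, 0.43, 0.34 and 0.53 and the share of rises 94.2%, 93.8%, 88.1% and 94.3%. Centring each array on its median gave 66.3%, 60.2%, 60.5% and 52.6%. The deposited values also differed in spread: the lower quartile of the arrays stood against 0 hpl at -0.20, -0.25, -0.15 and -0.26 (exact permutation p of 0.1 each) and the upper quartile at 0.13, 0.24, 0.17 and 0.21 (0.2, 0.1, 0.1 and 0.1). Changes are given relative to the deposited scale, and where the hybridisation-control scaling turns the median of a called list this is stated with it. That scaling adds the same amount to each change at a time, so it also turns list medians and gene changes that lie below 0 by less than this amount. RMA values carry no detection calls, so a fold for a single gene is given where the lower of the 2 group means lies above the median of the unlesioned arrays (4.63). A log2 change from a lower mean is not shown to start above background, and the order of the largest changes is that of the measured values.

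**Figure D2:**
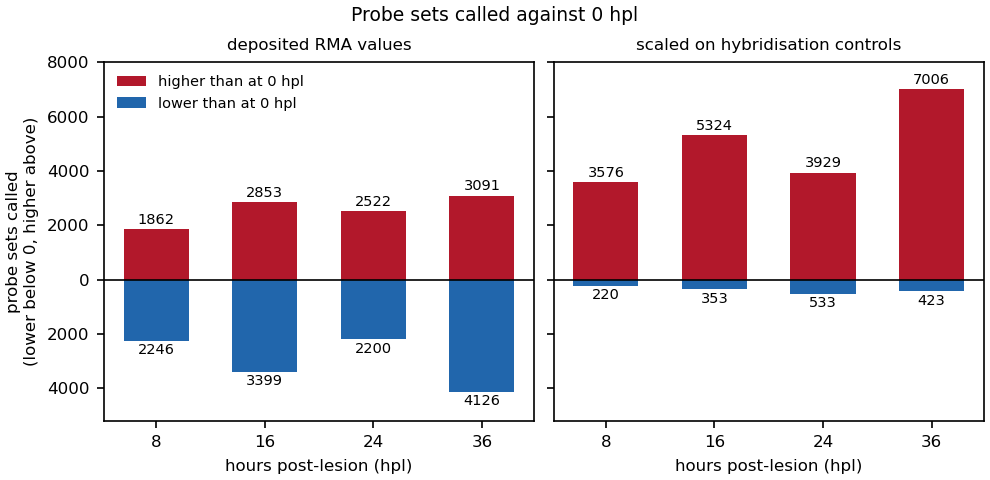
Bars count probe sets called at an adjusted p under 0.05 in each comparison, rises above 0 and falls below 0, on the deposited values at left and after scaling on the hybridisation controls at right. At 36 hpl 42.8% of calls are rises on the deposited values and 94.3% after that scaling.

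Gene names came from the authors' table of 3164 probe sets, and 3361 probe sets reached a 2-fold change at some time, so the named genes were selected by a change of at least 2-fold on these same samples. The direction and number of list members that rose or fell are therefore not independent evidence, and the list test compares each list with the other genes among the 2331 named ones, whose median change was 0.37, 0.84, 0.81 and 1.02. The authors' deposited table gave p-values under 0.05 for 61, 213, 275 and 326 probe sets at 8, 16, 24 and 36 hpl, and all of them were called here in the same direction, among 2007, 2681, 2584 and 2886 of that table's probe sets called here. With an inter-gene correlation estimated per list, no list was called against 0 hpl at any time. At the preset correlation 12, 15, 14 and 16 lists were called at the 4 times. Other divisions of the same arrays called up to 11, 14, 16 and 16. Those divisions mix the times unevenly and so keep part of the time difference. They cannot decide whether a list call is tied to the lesion. The calls at the preset correlation do not by themselves show it.

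The comparison of 8 hpl with 0 hpl asked for the earliest response of the sorted glia. The suppressor of cytokine signalling socs3b rose 34.9-fold (log2 change 5.13 ± 0.24 SE, adjusted p = 2.51e-09, n = 3 per group), and the matrix metallopeptidase mmp9 rose as well (4.06 ± 0.49 SE, adjusted p = 2.54e-05). The connective tissue growth factor gene ctgf (5.01 ± 0.42 SE) and the complement gene c6.2 (4.37 ± 0.42 SE) were higher too, as were the nucleolar chaperone npm1a (3.62 ± 0.18 SE), the major vault protein mvp (3.47 ± 0.15 SE) and the Myc family gene mych (3.46 ± 0.26 SE). The 6 largest falls were in the lysyl oxidase homologue loxl2b (-3.37 ± 0.28 SE), the circadian repressor ciarta (-3.03 ± 0.29 SE), the threonine dehydrogenase tdh (-2.70 ± 0.21 SE), the HIF prolyl hydroxylase egln3 (-2.56 ± 0.28 SE), the matrix-associated abi3bpb (-2.53 ± 0.28 SE) and the glial calcium-binding protein s100b (-2.53 ± 0.27 SE). Each of these genes had all 3 lesioned arrays outside the range of the controls.

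Lists for making and folding protein were called higher at 8 hpl. Of 54 named members of the ribosome biogenesis list 49 rose (49 adjusted over the list alone) and none fell, among them gnl3 (2.72 ± 0.17 SE), dkc1 (2.17 ± 0.17 SE) and wdr43 (1.67 ± 0.13 SE). Their median was 1.26, with a camera adjusted p of 2.38e-08 and adjusted p = 0.327 with an estimated correlation. Of 31 chaperones 26 rose and 4 fell (the same adjusted over the list alone). These included the ER chaperone hspa5 (2.49 ± 0.17 SE) and the mitochondrial co-chaperonin hspe1 (1.97 ± 0.20 SE), and the panel gene hspd1, the matching chaperonin, rose too (log2 change 1.31 ± 0.18 SE, adjusted p = 6.86e-05). A median of 1.02 gave a camera adjusted p of 0.00778, and adjusted p = 0.327 with an estimated correlation. The ER stress and amino-acid response list had 25 rises and 4 falls among 34 members (the same adjusted over the list alone), with hyou1 at 2.54 ± 0.21 SE and the serine-synthesis enzyme phgdh at -1.29 ± 0.13 SE. Camera gave 0.00778 as adjusted p for a median of 1.14, and adjusted p = 0.327 with an estimated correlation. Of 73 cytosolic ribosomal proteins 26 rose and 1 fell (35 and 1 adjusted over the list alone), rps6 among the rises (1.05 ± 0.15 SE). Their median was 0.50, with a camera adjusted p of 0.0375 and adjusted p = 0.762 with an estimated correlation.

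Immediate early genes and Jak-Stat signalling were called higher with them. In the immediate early and AP-1 list 13 of 23 members rose and 1 fell (13 and 1 adjusted over the list alone), including the kinase sgk1 (3.03 ± 0.13 SE) and the AP-1 subunit fosl2 (2.29 ± 0.15 SE). A median of 1.28 gave a camera adjusted p of 0.0186, and adjusted p = 0.48 with an estimated correlation. The Jak-Stat and inflammatory list had 11 rises and 2 falls among 14 (11 and 2 adjusted over the list alone), with the kinase pim1 at 2.81 ± 0.20 SE and irf9 at 1.66 ± 0.19 SE. Camera gave 0.0186 as adjusted p for a median of 1.45, and adjusted p = 0.327 with an estimated correlation. Of the panel, stat3 (1.05 ± 0.24 SE), socs3a (1.33 ± 0.24 SE), the stress factor atf3 (2.50 ± 0.26 SE), the proneural factor ascl1a (1.68 ± 0.23 SE) and the progenitor factor sox2 (1.06 ± 0.14 SE) rose, each with an adjusted p under 0.05. The Müller glia reprogramming list had 13 rises and 2 falls among 24 (13 and 4 adjusted over the list alone) and did not pass the list test. Their median was 0.68, with a camera adjusted p of 0.356 and adjusted p = 0.762 with an estimated correlation. Its members tgif1 (2.13 ± 0.14 SE) and sox4a (2.61 ± 0.18 SE) rose and the retinal homeobox gene rx2 fell (-1.85 ± 0.24 SE).

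Lists of Müller glia identity, hypoxia, retinoic acid and the clock were called lower at 8 hpl. Of 13 named Müller glia identity genes 8 fell and 1 rose (the same adjusted over the list alone), with the water channel aqp1a.1 at -1.18 ± 0.14 SE, the retinaldehyde-binding protein rlbp1a at -0.99 ± 0.17 SE and the glutamine synthetase glula at -0.45 ± 0.16 SE. The median of -0.46 was nearly undone by the hybridisation-control scaling. It gave a camera adjusted p of 0.00778, and adjusted p = 0.327 with an estimated correlation. The glycolysis and hypoxia list had 6 falls and 1 rise among 12 (6 and 1 adjusted over the list alone). Both hif1al (-1.63 ± 0.20 SE) and pdk4 (-2.26 ± 0.29 SE) fell. Camera gave 0.00833 as adjusted p for a median of -0.64, and adjusted p = 0.327 with an estimated correlation. The retinoic acid list had 7 falls and 2 rises among 11 (8 and 2 adjusted over the list alone), with the degrading enzyme cyp26a1 (-1.38 ± 0.22 SE), also on the identity list, and the synthesis gene rdh10b (1.37 ± 0.23 SE). Their median was -0.94, with a camera adjusted p of 0.0136 and adjusted p = 0.327 with an estimated correlation. Of 11 circadian clock genes 6 fell and 2 rose (6 and 2 adjusted over the list alone). A median of -0.61 gave a camera adjusted p of 0.0283, and adjusted p = 0.327 with an estimated correlation. Among these nr1d2b fell (-2.49 ± 0.24 SE) and nfil3-5 rose (3.02 ± 0.30 SE).

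Some mitosis and DNA replication genes fell at 8 hpl on the deposited scale, and the direction of both lists depended on the scaling. Of these, 10 of 36 mitosis genes fell and none rose (the same adjusted over the list alone), but with the hybridisation-control scaling the median turned above 0. Camera gave 0.000818 as adjusted p for a median of -0.39, and adjusted p = 0.192 with an estimated correlation. Likewise 4 of 25 DNA replication genes fell and none rose (3 adjusted over the list alone), and that scaling turned the median and ended the call. Their median was -0.22, with a camera adjusted p of 0.0283 and adjusted p = 0.672 with an estimated correlation. Markers of other cells were measured beside these groups. The 20 photoreceptor genes had 5 falls and 2 rises (the same adjusted over the list alone), the rod gene gnat1 (0.77 ± 0.31 SE, adjusted p = 0.0792) did not pass, and the cone gene gnat2 fell (-1.02 ± 0.24 SE). A median of -0.19 gave a camera adjusted p of 0.131, and adjusted p = 0.754 with an estimated correlation. Of 7 genes of other retinal neurons 5 rose and none fell (6 adjusted over the list alone), with vsx1 at 1.53 ± 0.29 SE and the GABA-synthesis gene gad1b at 1.18 ± 0.28 SE. Camera gave 0.288 as adjusted p for a median of 1.06, and adjusted p = 0.754 with an estimated correlation. The ribosomal protein call ended without 0 hpl replicate 2 or 8 hpl replicate 3, with adjusted p up to 0.422, and under repeated quantile normalisation, which also ended the DNA replication call. Leaving out the 3 arrays of lowest weight ended the ribosomal protein call too.

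The comparison of 16 hpl with 0 hpl came next. The gene mmp9 stood above the control level (log2 change 7.53 ± 0.49 SE, adjusted p = 2.78e-08, n = 3 per group), as did ctgf (6.32 ± 0.42 SE) and socs3b (5.29 ± 0.24 SE, 39.2-fold). The retinoid desaturase cyp27c1 (5.03 ± 0.31 SE), c6.2 (4.85 ± 0.42 SE), the kininogen kng1 (3.95 ± 0.23 SE) and the vesicle protein syt4 (3.93 ± 0.27 SE) rose as well. The largest falls were in loxl2b (-3.26 ± 0.28 SE), the collagen col9a2 (-3.24 ± 0.29 SE), the transcription factor atoh8 (-3.14 ± 0.35 SE), the syntaxin-binding stxbp6l (-3.08 ± 0.20 SE), s100b (-2.98 ± 0.27 SE) and cyp26a1 (-2.83 ± 0.22 SE). Of the panel, ascl1a (2.81 ± 0.23 SE), stat3 (0.84 ± 0.24 SE), socs3a (1.77 ± 0.24 SE), atf3 (1.59 ± 0.26 SE), sox2 (0.85 ± 0.14 SE) and the cyclin gene ccnd1 (1.02 ± 0.17 SE) rose.

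Lists for protein synthesis, folding and turnover were called higher at 16 hpl. The ribosome biogenesis list had 53 rises among 54 (54 adjusted over the list alone), with gnl3 at 3.22 ± 0.17 SE and pwp2h at 2.58 ± 0.16 SE. Their median was 1.71, with a camera adjusted p of 1.6e-07 and adjusted p = 0.256 with an estimated correlation. Of 73 ribosomal proteins 71 rose (71 adjusted over the list alone), rps6 by 2.15 ± 0.15 SE and rpl21 by 2.31 ± 0.19 SE. A median of 1.41 gave a camera adjusted p of 5.25e-07, and adjusted p = 0.416 with an estimated correlation. Of 31 chaperones 27 rose and 2 fell (the same adjusted over the list alone), with hspe1 at 2.78 ± 0.20 SE, the co-chaperone ptges3b at 2.41 ± 0.17 SE and hspd1 at 1.84 ± 0.18 SE. Camera gave 0.000707 as adjusted p for a median of 1.77, and adjusted p = 0.256 with an estimated correlation. The ER stress list had 30 rises and 1 fall among 34 (30 and 2 adjusted over the list alone), including hyou1 (3.42 ± 0.21 SE) and the disulphide isomerase pdia4 (2.28 ± 0.18 SE). Their median was 1.75, with a camera adjusted p of 0.000702 and adjusted p = 0.256 with an estimated correlation. Of 33 proteasome genes 30 rose and none fell (32 adjusted over the list alone), psmd11b by 1.85 ± 0.12 SE. A median of 1.21 gave a camera adjusted p of 0.000848, and adjusted p = 0.256 with an estimated correlation. The oxidative phosphorylation list had 24 rises and 1 fall among 31 (26 and 1 adjusted over the list alone), cycsb among them (2.73 ± 0.16 SE). Camera gave 0.021 as adjusted p for a median of 0.93, and adjusted p = 0.646 with an estimated correlation.

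Identity, metabolic and matrix lists were called lower. Of 13 Müller glia identity genes 9 fell and 1 rose (the same adjusted over the list alone). Their median was -0.78, with a camera adjusted p of 0.00139 and adjusted p = 0.256 with an estimated correlation. The riser was the second glutamine synthetase glulb (1.87 ± 0.23 SE), while glula (-0.74 ± 0.16 SE) and rlbp1a (-1.30 ± 0.17 SE) fell. The retinoic acid list had 7 falls and 1 rise among 11 (7 and 1 adjusted over the list alone), and the receptor gene raraa fell (-1.90 ± 0.22 SE). A median of -0.96 gave a camera adjusted p of 0.00383, and adjusted p = 0.256 with an estimated correlation. The glycolysis and hypoxia list had 9 falls and 2 rises among 12 (9 and 2 adjusted over the list alone), pdk4 falling (-2.37 ± 0.29 SE) and the lactate transporter slc16a3b rising (1.59 ± 0.16 SE). Camera gave 0.0132 as adjusted p for a median of -0.97, and adjusted p = 0.327 with an estimated correlation. Of 7 cholesterol and lipid synthesis genes 4 fell (4 falls and 1 rise adjusted over the list alone), the desaturase fads2 at -2.38 ± 0.24 SE. Their median was -0.92, with a camera adjusted p of 0.0403 and adjusted p = 0.349 with an estimated correlation. The extracellular matrix list had 11 falls and 5 rises among 21 (11 and 5 adjusted over the list alone), the risers including mmp9 and adam9a (1.94 ± 0.14 SE). A median of -0.83 gave a camera adjusted p of 0.018, and adjusted p = 0.256 with an estimated correlation. The FGF, TGF-beta and BMP list had 8 falls and 3 rises among 15 (9 and 3 adjusted over the list alone), with id3 at -1.80 ± 0.16 SE and the receptor gene fgfr2 at -1.42 ± 0.20 SE. Camera gave 0.0132 as adjusted p for a median of -0.65, and adjusted p = 0.273 with an estimated correlation. Of 11 clock genes 6 fell and 1 rose (8 and 1 adjusted over the list alone), tefa at -1.03 ± 0.14 SE. Their median was -0.76, with a camera adjusted p of 0.0407 and adjusted p = 0.256 with an estimated correlation.

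Of the 20 photoreceptor genes 11 fell and 1 rose at 16 hpl (12 and 1 adjusted over the list alone), with the blue cone opsin opn1sw2 at -1.57 ± 0.24 SE and gnat2 at -1.50 ± 0.24 SE, while gnat1 was at -0.52 ± 0.31 SE (adjusted p = 0.191). A median of -0.96 gave a camera adjusted p of 0.000702, and adjusted p = 0.349 with an estimated correlation. Of 36 mitosis genes 10 fell and 2 rose (9 and 2 adjusted over the list alone), the kinase aurka falling (-1.03 ± 0.16 SE) and the lamin lmnb1 rising (1.14 ± 0.18 SE), and the hybridisation-control scaling turned that median above 0 and ended the call. Camera gave 0.00462 as adjusted p for a median of -0.24, and adjusted p = 0.256 with an estimated correlation. The replication genes pcna (0.09 ± 0.14 SE, adjusted p = 0.649) and mcm5 (-0.29 ± 0.25 SE, adjusted p = 0.358) did not pass. Leaving out single arrays ended 3 list calls, with adjusted p up to 0.06 for cholesterol synthesis (without 0 hpl replicate 1, 0 hpl replicate 2 or 16 hpl replicate 3), 0.0581 for oxidative phosphorylation (without 16 hpl replicate 3) and 0.0651 for the clock (without 0 hpl replicate 3 or 16 hpl replicate 3). Repeated quantile normalisation ended the mitosis and oxidative phosphorylation calls, and the clock call also ended with the hybridisation-control scaling and without the 3 arrays of lowest weight.

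The comparison of 24 hpl with 0 hpl followed. The gene mmp9 was above 0 hpl (log2 change 7.76 ± 0.49 SE, adjusted p = 1.98e-08, n = 3 per group), and so was cyp27c1 (log2 change 5.90 ± 0.31 SE, adjusted p = 3.2e-09). Other large rises were in socs3b (4.83 ± 0.24 SE), the annexin anxa2a (4.76 ± 0.42 SE), kng1 (4.60 ± 0.23 SE), ascl1a (4.09 ± 0.23 SE) and the tubulin tuba1b (3.19 ± 0.17 SE). The falls were led by stxbp6l (-4.30 ± 0.20 SE), col9a2 (-3.47 ± 0.29 SE), loxl2b (-3.29 ± 0.28 SE), s100b (-3.09 ± 0.27 SE), cyp26a1 (-2.98 ± 0.22 SE) and the matrix glycoprotein tenascin R, tnr (-2.86 ± 0.30 SE). Of 25 DNA replication genes 14 rose and none fell (the same adjusted over the list alone), and the list did not pass its test. Their median was 0.76, with a camera adjusted p of 0.115 and adjusted p = 0.709 with an estimated correlation. Its members included the origin recognition gene orc6 (3.88 ± 0.20 SE), the helicase subunits mcm4 (2.17 ± 0.24 SE) and mcm5 (1.37 ± 0.25 SE), and the sliding clamp pcna (1.32 ± 0.14 SE). Of 11 G1/S regulators 7 rose and 2 fell (7 and 2 adjusted over the list alone), ccnd1 rising (2.12 ± 0.17 SE) and the Myc antagonist mxi1 falling (-1.97 ± 0.18 SE). A median of 0.67 gave a camera adjusted p of 0.829, and adjusted p = 0.901 with an estimated correlation.

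All 54 ribosome biogenesis genes rose at 24 hpl (54 adjusted over the list alone), with npm1a at 3.85 ± 0.18 SE. Camera gave 6.34e-08 as adjusted p for a median of 1.77, and adjusted p = 0.282 with an estimated correlation. All 73 ribosomal proteins rose (73 adjusted over the list alone), rpl27a by 2.12 ± 0.17 SE. Their median was 1.69, with a camera adjusted p of 9.31e-09 and adjusted p = 0.313 with an estimated correlation. All 33 proteasome genes rose too (33 adjusted over the list alone), psmb1 by 1.74 ± 0.15 SE. A median of 1.23 gave a camera adjusted p of 0.000225, and adjusted p = 0.282 with an estimated correlation. Of 31 chaperones 26 rose and 3 fell (27 and 3 adjusted over the list alone), hspd1 rising by 1.65 ± 0.18 SE. Camera gave 0.00263 as adjusted p for a median of 1.65, and adjusted p = 0.282 with an estimated correlation. The ER stress list had 30 rises and 3 falls among 34 (the same adjusted over the list alone), the proline-synthesis enzyme aldh18a1 among the rises (1.69 ± 0.16 SE). Their median was 1.46, with a camera adjusted p of 0.00375 and adjusted p = 0.282 with an estimated correlation. Of 31 oxidative phosphorylation genes 24 rose and 1 fell (30 and 1 adjusted over the list alone), and the faller was cox4i2, a cytochrome oxidase isoform tied to hypoxia (-2.29 ± 0.18 SE). A median of 0.96 gave a camera adjusted p of 0.0161, and adjusted p = 0.645 with an estimated correlation.

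Of 13 identity genes 9 fell and 1 rose (12 and 1 adjusted over the list alone), with rlbp1a at -2.04 ± 0.17 SE, efhd1 at -1.70 ± 0.18 SE and glula at -0.77 ± 0.16 SE. Camera gave 0.000164 as adjusted p for a median of -1.29, and adjusted p = 0.282 with an estimated correlation. The retinoic acid list had 8 falls and 1 rise among 11 (9 and 1 adjusted over the list alone), including the dehydrogenase dhrs9 (-1.37 ± 0.21 SE). Their median was -0.89, with a camera adjusted p of 0.0032 and adjusted p = 0.282 with an estimated correlation. Falls outnumbered rises in glycolysis and hypoxia (7 against 2 of 12, 9 and 2 adjusted over the list alone), where pdk4 was at -2.69 ± 0.29 SE and pgam1a at 1.19 ± 0.14 SE. A median of -1.11 gave a camera adjusted p of 0.00681, and adjusted p = 0.282 with an estimated correlation. Falls likewise outnumbered rises in cholesterol synthesis (5 against 0 of 7, 5 and 0 adjusted over the list alone), with fads2 at -2.81 ± 0.24 SE. Camera gave 0.0218 as adjusted p for a median of -1.05, and adjusted p = 0.282 with an estimated correlation. In the extracellular matrix list falls numbered 13 and rises 5 of 21 (13 and 5 adjusted over the list alone), adam9a among the rises (1.95 ± 0.14 SE). Their median was -0.83, with a camera adjusted p of 0.01 and adjusted p = 0.282 with an estimated correlation. In the FGF, TGF-beta and BMP list 9 fell and 2 rose among 15 (10 and 3 adjusted over the list alone), fgf8a falling (-1.22 ± 0.20 SE) and fgf10a rising (1.85 ± 0.29 SE). A median of -0.71 gave a camera adjusted p of 0.0163, and adjusted p = 0.282 with an estimated correlation. Of 11 clock genes 6 fell and 1 rose (6 and 1 adjusted over the list alone), tipin rising (1.12 ± 0.18 SE) and rorab falling (-1.20 ± 0.27 SE). Camera gave 0.0218 as adjusted p for a median of -0.82, and adjusted p = 0.282 with an estimated correlation.

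Of the 20 photoreceptor genes 15 fell and 1 rose at 24 hpl (18 and 1 adjusted over the list alone), opn1sw2 at -2.29 ± 0.24 SE and gnat1 at -0.86 ± 0.31 SE. Their median was -1.33, with a camera adjusted p of 9.24e-05 and adjusted p = 0.282 with an estimated correlation. The reprogramming list had 11 rises and 6 falls among 24 (14 and 6 adjusted over the list alone), with sox4a at 3.15 ± 0.18 SE, while stat3 was at 0.56 ± 0.24 SE (adjusted p = 0.0925). A median of 0.63 gave a camera adjusted p of 0.742, and adjusted p = 0.879 with an estimated correlation. The panel genes socs3a (1.74 ± 0.24 SE), atf3 (1.60 ± 0.26 SE) and sox2 (0.62 ± 0.14 SE) rose.

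The comparison of 36 hpl with 0 hpl asked what had changed by the latest time, when genes of mitosis stood above the controls. The mitotic kinase genes plk1 (log2 change 3.90 ± 0.18 SE, adjusted p = 7e-10) and ttk (log2 change 2.99 ± 0.15 SE, adjusted p = 1.63e-09) rose, with n = 3 per group. The spindle gene tacc3 rose too (adjusted p = 6.45e-10). Of 36 mitosis genes 34 rose and none fell (the same adjusted over the list alone). Camera gave 1.34e-05 as adjusted p for a median of 2.06, and adjusted p = 0.0562 with an estimated correlation. All 25 named DNA replication genes rose (25 adjusted over the list alone), pcna by 2.71 ± 0.14 SE, the thymidylate synthase tyms by 3.59 ± 0.21 SE, the ribonucleotide reductase subunit rrm1 by 2.91 ± 0.19 SE and mcm5 by 2.32 ± 0.25 SE. Their median was 1.91, with a camera adjusted p of 0.000118 and adjusted p = 0.308 with an estimated correlation. Of 16 chromatin genes 15 rose and 1 fell (the same adjusted over the list alone), the histone chaperone ssrp1a by 2.44 ± 0.18 SE and the DNA methyltransferase dnmt3ba by 2.01 ± 0.17 SE. A median of 1.63 gave a camera adjusted p of 0.0129, and adjusted p = 0.324 with an estimated correlation. Of 11 G1/S regulators 9 rose and 2 fell (the same adjusted over the list alone), with ccnd1 at 2.26 ± 0.17 SE and skp2 at 2.33 ± 0.22 SE. Camera gave 0.275 as adjusted p for a median of 1.39, and adjusted p = 0.632 with an estimated correlation.

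The largest rises at 36 hpl were in mmp9 (7.64 ± 0.49 SE), anxa2a (6.17 ± 0.42 SE), cyp27c1 (5.12 ± 0.31 SE), the cyclin gene ccnf (4.94 ± 0.30 SE), ascl1a (4.67 ± 0.23 SE, 25.4-fold), kng1 (4.61 ± 0.23 SE), socs3b (4.41 ± 0.24 SE) and the matrix protein anos1b (4.40 ± 0.25 SE). The largest falls were in stxbp6l (-4.01 ± 0.20 SE), col9a2 (-3.33 ± 0.29 SE), loxl2b (-3.29 ± 0.28 SE), s100b (-2.98 ± 0.27 SE), the phosphatase pxylp1 (-2.81 ± 0.20 SE) and the synuclein sncgb (-2.77 ± 0.30 SE). Of the panel, socs3a (1.54 ± 0.24 SE), atf3 (1.74 ± 0.26 SE) and hspd1 (1.57 ± 0.18 SE) rose, as did sox2 (0.38 ± 0.14 SE, adjusted p = 0.0367), while stat3 was at 0.28 ± 0.24 SE (adjusted p = 0.36). Because the study followed up hspd1 and ttk from these arrays, their changes are not independent evidence either.

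The lists for protein production were called higher at 36 hpl too. All 54 ribosome biogenesis genes rose (the same adjusted over the list alone), npm1a by 3.92 ± 0.18 SE. Their median was 1.45, with a camera adjusted p of 4.5e-05 and adjusted p = 0.308 with an estimated correlation. All 73 ribosomal proteins rose (the same adjusted over the list alone), rps6 by 3.09 ± 0.15 SE. A median of 2.08 gave a camera adjusted p of 2e-09, and adjusted p = 0.308 with an estimated correlation. All 33 proteasome genes rose (the same adjusted over the list alone), psmb1 by 2.08 ± 0.15 SE. Camera gave 8.35e-05 as adjusted p for a median of 1.57, and adjusted p = 0.207 with an estimated correlation. Of 31 chaperones 27 rose and 2 fell (the same adjusted over the list alone), cct5 by 2.37 ± 0.18 SE. Their median was 1.57, with a camera adjusted p of 0.00483 and adjusted p = 0.308 with an estimated correlation. The ER stress list had 31 rises and 3 falls (the same adjusted over the list alone), ssr2 at 1.21 ± 0.12 SE. A median of 1.27 gave a camera adjusted p of 0.0222, and adjusted p = 0.32 with an estimated correlation. Of 31 oxidative phosphorylation genes 30 rose and 1 fell (the same adjusted over the list alone), cox5ab by 2.31 ± 0.14 SE. Camera gave 0.00311 as adjusted p for a median of 1.43, and adjusted p = 0.519 with an estimated correlation.

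Of 13 identity genes 11 fell and 1 rose at 36 hpl (the same adjusted over the list alone), with the gap junction gene gja1b at -1.19 ± 0.13 SE, rlbp1a at -1.77 ± 0.17 SE and glula at -1.10 ± 0.16 SE. Their median was -1.19, with a camera adjusted p of 6.49e-05 and adjusted p = 0.207 with an estimated correlation. Cholesterol synthesis had 5 falls and 1 rise among 7 (6 and 1 adjusted over the list alone), with the synthase hmgcs1 at -2.19 ± 0.21 SE and the demethylase cyp51 at -2.38 ± 0.29 SE. A median of -2.19 gave a camera adjusted p of 0.00483, and adjusted p = 0.3 with an estimated correlation. The retinoic acid list had 8 falls and 1 rise (the same adjusted over the list alone), the receptor gene rxrga among them (-1.30 ± 0.17 SE). Camera gave 0.00328 as adjusted p for a median of -1.04, and adjusted p = 0.3 with an estimated correlation. Glycolysis and hypoxia had 9 falls and 2 rises (the same adjusted over the list alone), epas1b falling (-1.62 ± 0.25 SE). Their median was -0.99, with a camera adjusted p of 0.0109 and adjusted p = 0.308 with an estimated correlation. The FGF, TGF-beta and BMP list had 10 falls and 1 rise (11 and 1 adjusted over the list alone), with fgf8b at -1.20 ± 0.17 SE and acvr2ba at -1.13 ± 0.20 SE. A median of -1.01 gave a camera adjusted p of 0.00114, and adjusted p = 0.234 with an estimated correlation. Of the clock genes 7 fell and 1 rose (the same adjusted over the list alone), cry1a at -1.47 ± 0.20 SE. Camera gave 0.0112 as adjusted p for a median of -0.96, and adjusted p = 0.234 with an estimated correlation. Of the photoreceptor genes 15 fell and 1 rose (18 and 1 adjusted over the list alone), gnat2 at -2.11 ± 0.24 SE and gnat1 at -1.26 ± 0.31 SE. Their median was -1.23, with a camera adjusted p of 4.5e-05 and adjusted p = 0.308 with an estimated correlation.

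**Figure D3:**
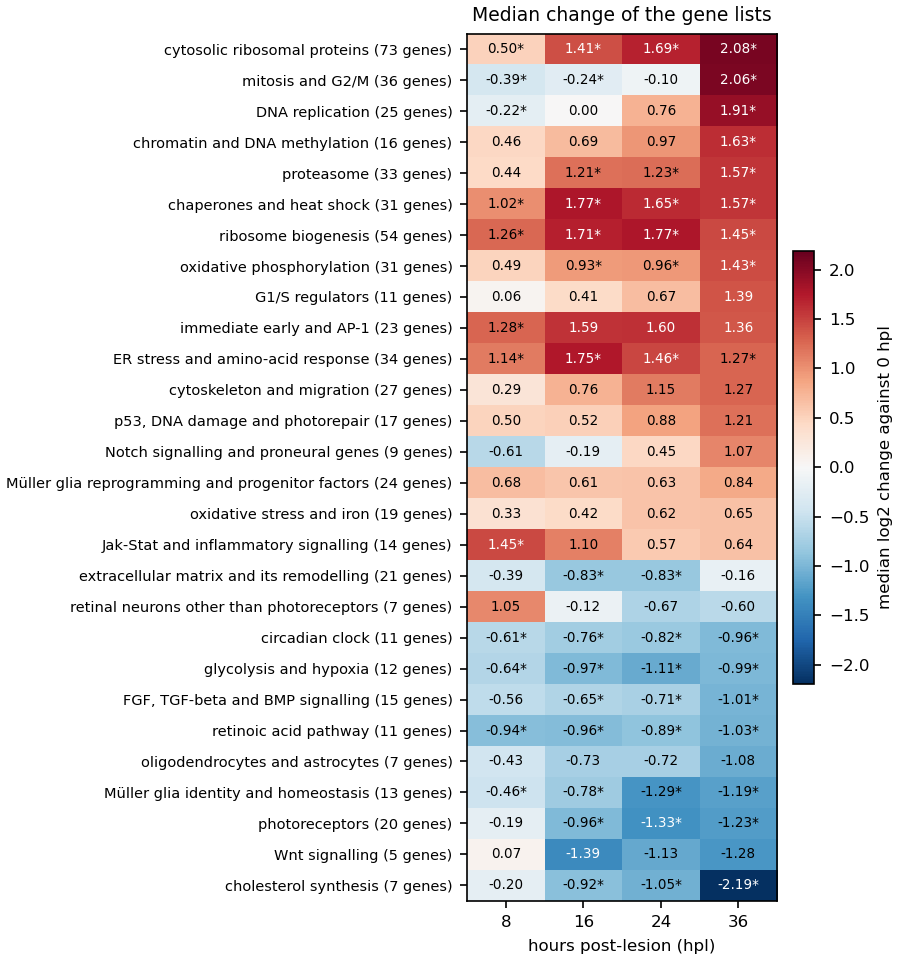
Each cell gives the median log2 change of a gene list against 0 hpl at 1 time, and an asterisk marks an adjusted p under 0.05 in camera with the preset correlation; the members were selected by a 2-fold change on these samples. Medians run from -2.19 for cholesterol synthesis to 2.08 for ribosomal proteins, both at 36 hpl. Among medians with an asterisk, those of DNA replication at 8 hpl and mitosis at 8 and 16 hpl turn above 0 when arrays are scaled on the hybridisation controls. Some medians without an asterisk turn as well.

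**Figure D4:**
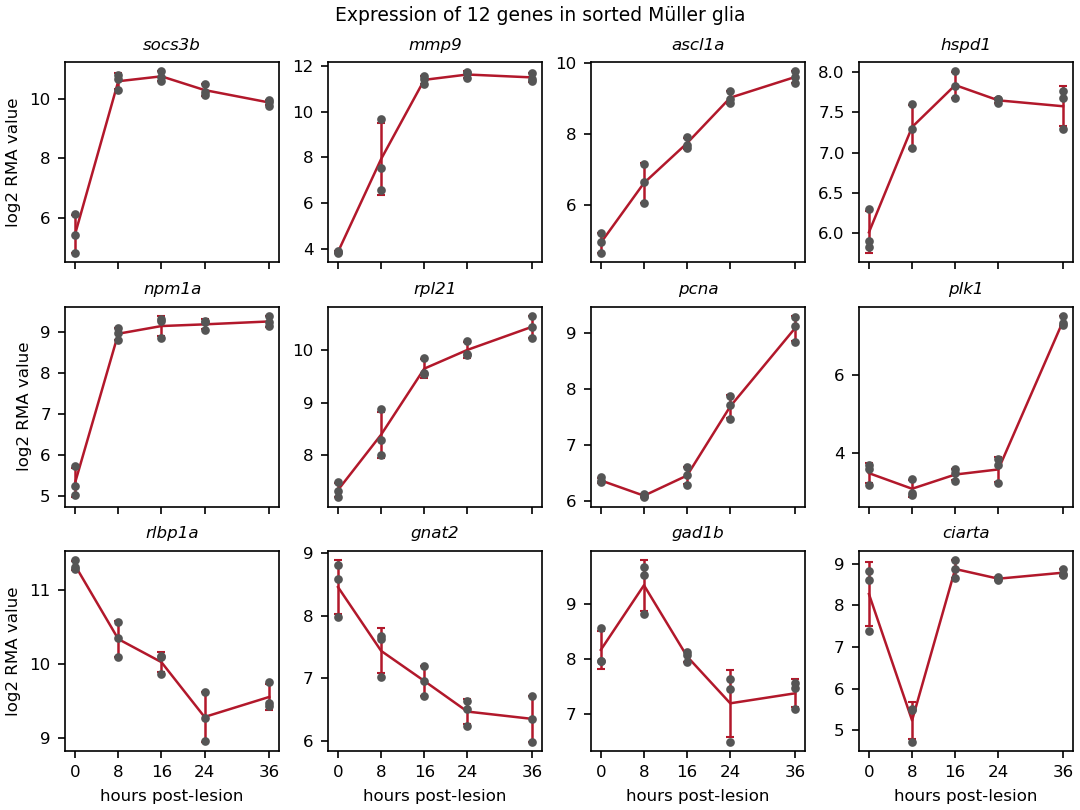
Log2 RMA values of 12 genes against hours post-lesion, where points are the 3 arrays of a group, lines join the means and bars show the SD. Against 0 hpl plk1 passes the test at 36 hpl and not at the earlier times, and mmp9 passes it at all 4 times.

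The comparison of 8 hpl with 16 hpl tested the difference between the times themselves, without the controls. It called 1332 probe sets, 849 higher and 483 lower at 16 hpl. Leaving out 16 hpl replicate 1, 2 or 3 gave 785, 866 or 815 calls, and rises made up between 47.2% and 74.7% of the calls over the alternatives. The largest rises were in ciarta (3.64 ± 0.29 SE, adjusted p = 6.01e-06), mmp9 (3.46 ± 0.49 SE), the collagen col15a1 (3.17 ± 0.29 SE) and anxa2a (2.72 ± 0.42 SE). The largest falls were in nfil3-5 (-3.79 ± 0.30 SE), stxbp6l (-2.46 ± 0.20 SE), the linker histone h1-10 (-2.45 ± 0.24 SE) and the rod transducin subunit gngt1 (-2.38 ± 0.42 SE).

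Lists for protein production were called higher at 16 than at 8 hpl. Of 73 ribosomal proteins 62 rose (70 adjusted over the list alone). A median of 0.86 gave a camera adjusted p of 3.96e-14, and adjusted p = 0.291 with an estimated correlation. Of 33 proteasome genes 23 rose (31 adjusted over the list alone). Camera gave 5.53e-06 as adjusted p for a median of 0.74, and adjusted p = 0.26 with an estimated correlation. Of 31 chaperones 17 rose (25 adjusted over the list alone). Their median was 0.71, with a camera adjusted p of 0.000135 and adjusted p = 0.26 with an estimated correlation. Of 34 ER stress genes 17 rose (27 adjusted over the list alone). A median of 0.67 gave a camera adjusted p of 0.000221, and adjusted p = 0.26 with an estimated correlation. Of 54 ribosome biogenesis genes 16 rose (25 adjusted over the list alone). Camera gave 0.00302 as adjusted p for a median of 0.44, and adjusted p = 0.47 with an estimated correlation.

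Lists of retinal neurons and of glial identity were called lower from 8 to 16 hpl, the latter with few members called. Of 7 genes of retinal neurons other than photoreceptors 4 fell (4 falls and 1 rise adjusted over the list alone). Their median was -1.30, with a camera adjusted p of 0.00535 and adjusted p = 0.291 with an estimated correlation. Of 20 photoreceptor genes 6 fell and 1 rose (12 and 1 adjusted over the list alone). A median of -0.65 gave a camera adjusted p of 7.86e-06, and adjusted p = 0.291 with an estimated correlation. The identity list had 2 falls (2 falls and 2 rises adjusted over the list alone), a call that ended without 16 hpl replicate 3 at an adjusted p of 0.0518. Camera gave 0.0163 as adjusted p for a median of -0.29, and adjusted p = 0.291 with an estimated correlation. The list test also called cholesterol synthesis lower, with no single member called and 6 falls adjusted over the list alone. Their median was -0.61, with a camera adjusted p of 0.00418 and adjusted p = 0.291 with an estimated correlation. Wnt signalling was called lower with 2 falls of 5 (the same adjusted over the list alone). A median of -0.30 gave a camera adjusted p of 0.0163, and adjusted p = 0.26 with an estimated correlation. Retinoic acid was called lower with 2 falls of 11 (3 adjusted over the list alone). Camera gave 0.0163 as adjusted p for a median of -0.31, and adjusted p = 0.291 with an estimated correlation. The FGF, TGF-beta and BMP list was called lower too (3 falls, 4 falls and 1 rise adjusted over the list alone), with a median that the hybridisation-control scaling turned above 0. Their median was -0.11, with a camera adjusted p of 0.0109 and adjusted p = 0.291 with an estimated correlation.

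From 16 to 24 hpl 87 probe sets were called, 45 higher and 42 lower at 24 hpl. The number was 24, 31 or 33 without 16 hpl replicate 1, 2 or 3 and 39, 33 or 51 without 24 hpl replicate 1, 2 or 3, and median centring turned the balance to 33 rises and 63 falls. Array weights gave 545 calls and the hybridisation-control scaling 18, and the share of rises lay between 34.4% and 83.3% over the alternatives. The largest rises were in cdca7a, which is on the mitosis list (log2 change 2.35 ± 0.28 SE, adjusted p = 0.00117), and in the DNA replication genes orc6 (log2 change 2.17 ± 0.20 SE, adjusted p = 0.000241), mcm4 (1.97 ± 0.24 SE) and mcm2 (1.94 ± 0.29 SE). The largest falls were in ctgf (-2.39 ± 0.42 SE), the small heat shock protein hspb6 (-1.43 ± 0.25 SE), stxbp6l (-1.21 ± 0.20 SE) and the kinase mapk14b (-1.08 ± 0.20 SE). Of 25 replication genes 9 rose and none fell (16 adjusted over the list alone). A median of 0.66 gave a camera adjusted p of 3.45e-17, and adjusted p = 0.0735 with an estimated correlation. Of 36 mitosis genes 1 rose (3 adjusted over the list alone). Camera gave 0.000619 as adjusted p for a median of 0.22, and adjusted p = 0.0735 with an estimated correlation. Of 27 cytoskeleton genes 3 rose (11 adjusted over the list alone). Their median was 0.32, with a camera adjusted p of 0.000475 and adjusted p = 0.0735 with an estimated correlation.

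No single ribosomal protein passed from 16 to 24 hpl, yet that list was called higher. A median of 0.28 gave a camera adjusted p of 4.76e-09, and adjusted p = 0.428 with an estimated correlation. The identity list was called lower with 1 fall (3 adjusted over the list alone). Camera gave 0.00645 as adjusted p for a median of -0.29, and adjusted p = 0.287 with an estimated correlation. The ER stress list was called lower with 0 falls (0 adjusted over the list alone). Their median was -0.24, with a camera adjusted p of 0.000657 and adjusted p = 0.287 with an estimated correlation. Jak-Stat signalling was called lower with 0 falls (1 adjusted over the list alone). A median of -0.32 gave a camera adjusted p of 0.015, and adjusted p = 0.328 with an estimated correlation. The remaining 6 called lists each lost the call without some array. For G1/S regulators (median 0.25) this was 24 hpl replicate 3, with an adjusted p of 0.0717. For photoreceptors (-0.35) it was 16 hpl replicate 1 or 3 or 24 hpl replicate 1 or 3, with up to 0.121. For immediate early genes (-0.29) it was 16 hpl replicate 1, with 0.0775. For the proteasome (0.17) it was 16 hpl replicate 1 or 24 hpl replicate 3, with up to 0.0949. For chromatin (0.29) and Notch signalling (0.18) it was 16 hpl replicate 3 or 24 hpl replicate 3, with up to 0.0624 and 0.0785. Other settings ended some of these calls as well: leaving out the dimmest 25% (G1/S, photoreceptors, Notch), median centring (photoreceptors), repeated quantile normalisation (Notch) and the hybridisation-control scaling (proteasome). With an estimated correlation their adjusted p lay between 0.287 and 0.699.

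From 24 to 36 hpl genes of mitosis rose. Of 36 named mitosis genes 35 rose and none fell (36 adjusted over the list alone). This was the list call that held with an estimated correlation (camera adjusted p = 7.06e-37, and adjusted p = 1.68e-05 with an estimated correlation). The cyclin gene ccnf (log2 change 4.19 ± 0.30 SE, 18.3-fold, adjusted p = 1.77e-07), rtkn2 (3.89 ± 0.25 SE), the spindle protein tacc3 (3.81 ± 0.19 SE) and the kinase plk1 (log2 change 3.80 ± 0.18 SE, adjusted p = 6.9e-09) rose most. The largest falls were in fgf10a (-2.53 ± 0.29 SE), ctgf (-1.91 ± 0.42 SE), hmgcs1 (-1.59 ± 0.21 SE) and the transcription factor creb3l3 (-1.37 ± 0.22 SE). Of 25 replication genes 18 rose (22 adjusted over the list alone). Camera gave 1.62e-12 as adjusted p for a median of 1.07, and adjusted p = 0.262 with an estimated correlation. Of 16 chromatin genes 6 rose (11 adjusted over the list alone). Their median was 0.72, with a camera adjusted p of 0.00079 and adjusted p = 0.472 with an estimated correlation. In all 797 probe sets were called, 482 higher and 315 lower, and the count was 450 or 345 without 24 hpl replicate 1 or 2 and 358 without 36 hpl replicate 2. Rises and falls numbered 278 and 67 without 24 hpl replicate 2, 300 and 58 without 36 hpl replicate 2, and 470 and 20 with the hybridisation-control scaling.

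Ribosomal proteins were called higher at 36 than at 24 hpl with 5 rises (5 adjusted over the list alone). A median of 0.38 gave a camera adjusted p of 2.12e-05, and adjusted p = 0.542 with an estimated correlation. Oxidative phosphorylation was called higher with 2 rises (3 adjusted over the list alone). Camera gave 0.0062 as adjusted p for a median of 0.41, and adjusted p = 0.602 with an estimated correlation. Ribosome biogenesis was called lower (2 falls, 3 adjusted over the list alone). Their median was -0.30, with a camera adjusted p of 3.2e-05 and adjusted p = 0.472 with an estimated correlation. Without some arrays 4 other calls ended, and leaving out the 3 arrays of lowest weight ended those of G1/S regulators, the proteasome and immediate early genes. Repeated quantile normalisation ended the proteasome call. G1/S regulators were called higher (5 rises, 6 adjusted over the list alone), with adjusted p up to 0.0575 without 24 hpl replicate 2 or 36 hpl replicate 2. A median of 0.54 gave a camera adjusted p of 0.0264, and adjusted p = 0.472 with an estimated correlation. The proteasome was called higher (0 rises, 0 adjusted over the list alone), with adjusted p up to 0.0903 without 24 hpl replicate 1 or 36 hpl replicate 2. Camera gave 0.0329 as adjusted p for a median of 0.28, and adjusted p = 0.472 with an estimated correlation. Immediate early genes were called lower (2 falls, 7 adjusted over the list alone), with adjusted p up to 0.0939 without 24 hpl replicate 1 or 2 or 36 hpl replicate 2 or 3. Their median was -0.24, with a camera adjusted p of 0.0388 and adjusted p = 0.542 with an estimated correlation. ER stress genes were called lower (0 falls, 0 adjusted over the list alone), with a median that the hybridisation-control scaling turned above 0 and an adjusted p of 0.0939 without 36 hpl replicate 3. A median of -0.21 gave a camera adjusted p of 0.023, and adjusted p = 0.472 with an estimated correlation.

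Many probe sets were called at more than 1 time against the same 3 controls. Of the rises 1862 were first called at 8 hpl, 1267 at 16 hpl, 251 at 24 hpl and 703 at 36 hpl, and of the falls 2246, 1574, 411 and 909. The rises shared by 8 and 16 hpl numbered 1586, where independent lists would share 343, those of 16 and 24 hpl 2263 (464), and those of 24 and 36 hpl 2174 (503). The shared falls numbered 1825 (492), 1724 (482) and 1825 (586). In simulations of unchanged groups against the same controls 0 calls were shared, the changes correlated across probe sets at 0.50 and their covariance was 0.02. The real changes correlated at 0.85, 0.93 and 0.87 for the same pairs of times, with covariances of 0.35, 0.48 and 0.49. With 3 controls the arrays cannot be divided between the comparisons, so part of the excess may come from the shared controls. At all 4 times 1262 probe sets were up and 1013 were down, and 155 were up at some time and down at another.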

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

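The tests of the 3 patterns weighed here and the rule that picked the 14 genes below were chosen after the results were seen. Of 235 named genes 14 were called in opposite directions at 2 times against 0 hpl, with a difference between those times that passed limma's test. In 10 of them the earlier change was negative and the later positive, and in 4 the reverse. Values are the later minus the earlier log2 change. From 8 to 36 hpl dut differed by 4.63 ± 0.27 SE (adjusted p = 8.44e-09), rrm2 by 4.42 ± 0.20 SE, tyms by 4.22 ± 0.21 SE and rpa2 by 2.44 ± 0.13 SE, all genes of DNA replication. Over the same times the mitosis genes ccna2 (2.86 ± 0.15 SE), cdc25b (2.78 ± 0.16 SE) and top2a (2.80 ± 0.14 SE) differed, as did the Notch ligand dld (2.59 ± 0.23 SE) and the cell-surface gene podxl (2.96 ± 0.19 SE). From 16 to 36 hpl ccnb1 differed by 2.06 ± 0.17 SE. The reverse order held for gad1b (-2.15 ± 0.28 SE, 8 to 24 hpl), gngt1 (-3.17 ± 0.42 SE, 8 to 36 hpl), h1-10 (-2.62 ± 0.24 SE, 8 to 24 hpl) and mapk14b (-1.90 ± 0.20 SE, 16 to 36 hpl). The adjusted p of the differences reached up to 0.000106. With the arrays scaled on the hybridisation controls 9 of the 14 lost the earlier call, gad1b and mapk14b lost the later one, and opposite calls stayed in rrm2, gngt1 and h1-10.

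Transcripts of inner retinal neurons were higher at 8 hpl, with 5 of 7 named members called and a list test that did not pass. The members with the highest array levels, which also depend on the probes, were atp1b2a (8.72 ± 0.23 SD at 0 hpl and 9.75 ± 0.47 SD at 8 hpl) and gad1b (8.17 ± 0.35 SD and 9.35 ± 0.46 SD), and vsx1 is also on the reprogramming list. The lowest median over 3 scalings, 0.94, cannot decide, as none could lower it much. A higher share of all other retinal cells in the sort stays open. The cone markers had a median change of -0.94 with 5 of 8 lower, while 7 rod markers were at 0.56 with 1 higher and 0 lower. Cone markers were lower at 16 and 24 hpl too (medians -1.39 and -1.62). Lower cone transcripts in the retina itself could therefore hide such a share, which was not tested. RNA of inner neurons carried through the GFP sort stays open, since elavl3 changed by -0.23 ± 0.44 SE, too wide a spread to decide. A response of the glia to the lesion stays open too and was not tested.

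From the 11 named clock genes 4 were picked by a call of at least 2-fold at 8 hpl and again from 8 to 16 hpl. Changes at both points were thus fixed by the pick. The list as a whole did not move back, with medians of -0.61, -0.76, -0.82 and -0.96 at the 4 times. The picked genes ciarta, bhlhe41, nr1d2b and nfil3-5 differed from 0 hpl at 8 hpl and moved back toward it from 8 to 16 hpl. Of these nr1d2b was still called at the 3 later times and the others at none of them. Scaling does not remove the changes of these picked genes at 8 hpl, whose smallest absolute value over 3 scalings was 1.78. That outcome was close to fixed, because the hybridisation controls stood at -0.44 at 8 hpl, a shift small beside these changes. The time of day at dissection is a candidate explanation. The median absolute change of the 4 picked genes at 24 hpl was 0.43, but clock time is tied to hours post-lesion and not given in the sources used here. It therefore cannot be told apart from an effect of the lesion.

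Fewer rises than falls were called at 36 hpl, where 42.8% of calls were rises. Without the dimmest 25% of probe sets 47.1% were rises (3000 against 3366 falls, from 3091 against 4126). Falls of dim probe sets thus make up much of the excess, and falls still outnumbered rises without them. Leaving out single arrays moved the share as far as 48.8%, so whether the remaining excess goes beyond that spread cannot be told. The scaling of the arrays may account for the balance, because 94.3% were rises when arrays were scaled on the hybridisation controls. Which scale holds stays open: a different amount of labelled RNA on the arrays and a real difference in total RNA could shift these controls alike, and no test here separates them.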

How the results depend on the processing

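The hybridisation-control scaling and the omission of the 3 arrays with the lowest weights (0 hpl replicate 3, 8 hpl replicate 3 and 36 hpl replicate 2) were chosen after the results were seen. Among 964 log2 changes of 235 named genes, 811 of them called, the direction and side of the threshold stayed for 909 under repeated quantile normalisation, 923 under median centring, 717 under hybridisation-control scaling, 959 with a variance trend, 948 with replicate number as a block and 924 on the compared groups alone. Leaving out single arrays kept 5450 of 5784 values, with no called value reversed. Replicate numbers did not pair the arrays (mean correlation of deviations -0.016 within a number). RMA values give no signal-over-background call, so what dim probe sets limit could not be read from them.

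Where counts moved by more than 1.5 times, the stricter thresholds lower them by construction and for the other settings the cause was not tested. With a 2-fold minimum the counts were 1052, 1953, 1959 and 2508 at 8, 16, 24 and 36 hpl and 377, 42 and 277 for the steps 8 to 16, 16 to 24 and 24 to 36 hpl. At an adjusted p under 0.01 they were 1948 at 8 hpl, 3969 at 16 hpl and 550, 24 and 309 for the steps. Fits on the compared groups alone, with fewer arrays, gave 2354 at 8 hpl and 806 and 142 for the first and second step. Array weights gave 2078, 545 and 1207 for the steps, hybridisation-control scaling 637, 18 and 490, the replicate block 55 for 16 to 24 hpl, and 3 arrays fewer 158 and 518 for the last 2 steps. Leaving out 1 array gave 785 to 1228, 24 to 51 and 345 to 832 for the steps, 2992 to 3867, 4899 to 5982, 3640 to 4434 and 5787 to 6846 for the 4 times and 6096 to 7288 for the F test. The low ends came without 16 hpl replicate 1 for the first and second step and without 24 hpl replicate 2 for the third.

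Counts at an adjusted p under 0.01 follow. The overlap of calls between times: up at 8 and 16 hpl was 1009, the overlap of calls between times: up at 8 and 24 hpl 907 and the overlap of calls between times: up at 8 and 36 hpl 851. For falls the overlap of calls between times: down at 8 and 16 hpl was 652, the overlap of calls between times: down at 8 and 24 hpl 488 and the overlap of calls between times: down at 8 and 36 hpl 632. Among later times the overlap of calls between times: down at 16 and 24 hpl was 946, the overlap of calls between times: down at 16 and 36 hpl 1495 and the overlap of calls between times: down at 24 and 36 hpl 1007. With an estimated correlation camera called 0 lists in each contrast except 24 to 36 hpl, where it called 1, and the cause was not tested. Hybridisation-control scaling turned 8 called falls into changes above 0 that were not called, at 8 hpl gja1b (0.067) and tpi1b (0.102), at 16 hpl ccna2 (0.035), cdc25b (0.056), nfil3-6 (0.006) and top2a (0.077), and at 36 hpl mapk14b (0.115) and mbd3b (0.035). Each was a fall smaller than the amount that scaling adds at its time.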

Other observations

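The tests below on divisions of the arrays were written after the counts for the real times were seen and before those of the other divisions, and the list tests were chosen before the data were examined. Signalling lists without a call against 0 hpl held members that moved apart. In the Wnt list 2 of 5 rose and 3 fell at 16 hpl, the same numbers adjusted over the list alone (median -1.39, camera adjusted p = 0.137), with wnt11 at -2.47 ± 0.23 SE, sp5a at -2.29 ± 0.29 SE and the co-repressor tle3b at 0.92 ± 0.22 SE. At 36 hpl the Notch and proneural list had 6 rises and 3 falls among 9 (6 and 3 adjusted over the list alone, median 1.07, camera adjusted p = 0.798). Its ligand genes dlc (1.22 ± 0.11 SE) and dld (1.44 ± 0.23 SE) rose and the glycosyltransferase lfng fell (-1.07 ± 0.14 SE). The p53 and DNA damage list had 12 rises and 5 falls among 17 at 36 hpl (12 and 5 adjusted over the list alone, median 1.21, camera adjusted p = 0.659), with gadd45bb at 1.98 ± 0.19 SE. The oxidative stress and iron list had 11 rises and 8 falls among 19 (11 and 8 adjusted over the list alone, median 0.65, camera adjusted p = 0.538), and gstp1.2 fell (-1.49 ± 0.14 SE). The cytoskeleton list had 21 rises and 6 falls among 27 (21 and 6 adjusted over the list alone, median 1.27, camera adjusted p = 0.087), with the tubulins tuba5 at 4.28 ± 0.13 SE and tubb5 at 3.72 ± 0.20 SE.

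Markers of other cell types were mostly lower. At 36 hpl the leukocyte-associated cd9b, the named member of its list, fell (-1.96 ± 0.19 SE). On the red blood cell list hbae3 (-1.62 ± 0.21 SE) and cahz (-1.48 ± 0.20 SE) fell, and cahz is also on the Müller glia identity list. Lower too were the lens crystallins cryba4 (-2.60 ± 0.18 SE) and cryaba (-1.51 ± 0.16 SE), and the pigment epithelium gene rpe65a (-1.65 ± 0.58 SE). Of the endothelial and mural genes podxl rose (2.43 ± 0.19 SE), as did cldn5a (adjusted p = 0.000688), and rgs5a (-1.52 ± 0.22 SE) and kdrl (-1.19 ± 0.34 SE) fell. The complement list held c6.2, which rose at each time and stood at 2.37 ± 0.42 SE at 36 hpl. These lists had fewer than 5 named members and no list test. The oligodendrocyte and astrocyte list had 3 rises and 3 falls among 7 (median -1.08, camera adjusted p = 0.538), with krt18a.1 at 4.24 ± 0.33 SE, a keratin also on the cytoskeleton list, and sox10 at -1.28 ± 0.20 SE. Its mean, 0.49, had the opposite sign of its median, as in the extracellular matrix list at 36 hpl (0.41 against -0.16). For p53 at 8 hpl, Notch at 24 hpl and oxidative stress at 16, 24 and 36 hpl the median was above 0 and the camera direction lower, since camera compares a list with the other named genes. Control probe sets for EGFP lay at 3.47 ± 0.23 SD at 0 hpl, lower by 0.37 at 8 hpl (exact permutation p = 0.2), 3.18 ± 0.13 SD at 16 hpl, 3.39 ± 0.19 SD at 24 hpl and 3.24 ± 0.33 SD at 36 hpl (n = 3 each), below the median of the arrays. Whether these probes match the transgene is not given in the sources used here, so neither GFP content nor sort purity can be read from them. In 8 hpl replicate 3 the GAPDH probe sets of the 3' and 5' ends differed by 0.41, against -0.08 and -0.18 in the other arrays of its time, its array weight was 0.37, and it stood at 33.3 on the third principal component against 4.88 and 4.77.

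Lists without a call at the remaining times follow, where parentheses hold the counts adjusted over the list alone, the median and the adjusted p of camera. Of 9 Notch and proneural genes there were 2 up and 4 down at 8 hpl (2 and 6, -0.61, 0.0876), 2 up and 3 down at 16 hpl (2 and 3, -0.19, 0.287) and 3 up and 3 down at 24 hpl (5 and 3, 0.45, 0.768). Of 5 Wnt genes there were 2 up and 1 down at 8 hpl (2 and 1, 0.07, 0.646), 2 up and 3 down at 24 hpl (2 and 3, -1.13, 0.227) and 2 up and 3 down at 36 hpl (2 and 3, -1.28, 0.236). Of 17 p53 and DNA damage genes there were 7 up and 4 down at 8 hpl (7 and 4, 0.50, 0.753), 9 up and 3 down at 16 hpl (9 and 3, 0.52, 0.938) and 11 up and 5 down at 24 hpl (12 and 5, 0.88, 0.816). Of 19 oxidative stress and iron genes there were 7 up and 1 down at 8 hpl (7 and 1, 0.33, 0.702), 10 up and 7 down at 16 hpl (10 and 8, 0.42, 0.614) and 10 up and 8 down at 24 hpl (10 and 8, 0.62, 0.483). Of 27 cytoskeleton genes there were 11 up and 5 down at 8 hpl (12 and 5, 0.29, 0.719), 17 up and 5 down at 16 hpl (18 and 5, 0.76, 0.418) and 19 up and 4 down at 24 hpl (20 and 6, 1.15, 0.115). The 7 oligodendrocyte and astrocyte genes had 3 up and 2 down at 8 hpl (3 and 2, -0.43, 0.719), 3 up and 3 down at 16 hpl (3 and 3, -0.73, 0.662) and 3 up and 3 down at 24 hpl (3 and 3, -0.72, 0.741). Camera with an estimated correlation gave adjusted p from 0.282 to 0.956 for these lists and times.

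Lists called in other comparisons were not called at these times, with parentheses as before (counts adjusted over the list alone, median, adjusted p of camera). Of 16 chromatin genes there were 8 up and 1 down at 8 hpl (8 and 1, 0.46, 0.719), 9 up and 1 down at 16 hpl (9 and 1, 0.69, 0.45) and 12 up and 1 down at 24 hpl (12 and 1, 0.97, 0.154). The 23 immediate early genes had 16 up and 2 down at 16 hpl (16 and 2, 1.59, 0.0928), 16 up and 5 down at 24 hpl (16 and 6, 1.60, 0.273) and 14 up and 6 down at 36 hpl (14 and 7, 1.36, 0.702). The 14 Jak-Stat genes had 11 up and 2 down at 16 hpl (11 and 2, adjusted p 0.181), 8 up and 3 down at 24 hpl (9 and 3, 0.57, 0.483) and 6 up and 2 down at 36 hpl (7 and 2, 0.64, 0.795). Of 11 G1/S regulators there were 2 up and 3 down at 8 hpl (4 and 3, 0.06, 0.549) and 5 up and 3 down at 16 hpl (5 and 3, 0.42, 0.662). Of 7 genes of inner retinal neurons there were 2 up and 0 down at 16 hpl (2 and 0, -0.12, 0.614), 0 up and 1 down at 24 hpl (0 and 1, -0.67, 0.227) and 1 up and 1 down at 36 hpl (1 and 1, -0.60, 0.244). The 21 extracellular matrix genes had 5 up and 8 down at 8 hpl (6 and 10, -0.39, 0.057) and 7 up and 9 down at 36 hpl (7 and 9, -0.16, 0.101). At 8 hpl there were also 14 up and 0 down (14 and 0, 0.44, 0.144) among 33 proteasome genes, 13 up and 1 down (14 and 1, 0.49, 0.0632) among 31 of oxidative phosphorylation, 1 up and 1 down (1 and 1, -0.20, 0.326) among 7 of cholesterol synthesis and 3 up and 7 down (3 and 9, -0.56, 0.0632) among 15 of FGF, TGF-beta and BMP. The 25 DNA replication genes had 4 up and 2 down at 16 hpl (4 and 2, 0.00, 0.334) and the 36 mitosis genes 3 up and 2 down at 24 hpl (3 and 0, -0.10, 0.115).

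Dividing the 15 arrays at random into 5 groups of 3 gave at most 531 calls by the F test over 99 other divisions, against 7136 for the real times, so that 1 of 100 divisions, the real one, reached that count. For each contrast the 10 divisions of its 6 arrays are too few for a share under 0.05. The real counts at 8, 16, 24 and 36 hpl were 4108, 6252, 4722 and 7217, and the highest of the other divisions gave 1, 0, 1 and 0. For the steps the real counts were 1332, 87 and 797 and the highest others 0, 1 and 0. For lists the real counts against 0 hpl were 12, 15, 14 and 16 and the highest others 11, 14, 16 and 16, with 1, 1, 4 and 2 of 10 divisions calling as many. For the steps they were 12, 13 and 10 against 13, 9 and 10, with 2, 1 and 2 of 10. Except from 16 to 24 hpl, the other divisions thus called nearly as many lists as the real times or more. They mix the times unevenly and so keep part of the time difference, and lists that changed with time can be called in them too. The divisions therefore cannot decide whether a list call comes from the time after the lesion. A list call at the preset correlation does not by itself show it.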
